A study of Drosophila melanogaster with 40 samples.

How the data were processed

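Whole adult flies were measured on 40 single-colour Affymetrix expression arrays for Drosophila. Per the series design, 5 mitochondrial strains (alstonville, brownsville, dahomey, japan and mysore) had each been introgressed independently into the w1118 nuclear background to give 2 lines, and each line was measured in each sex on 2 biological replicates, so that a strain and sex has 4 arrays. Per the labels, the replicate number of an array is its batch, 1 or 2, and every line and sex has 1 array in each batch. Total RNA had been extracted with Trizol and purified with RNeasy, per the labels' protocols.

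The expression matrix holds 1 value per probe set and array. The deposited values lie between 5.65 and 15.5 and were taken as log2 values because of that range; background correction, normalization and summarisation by the authors are not given in the sources used here. Array medians lay between 7.30 and 7.36 in males and between 6.76 and 6.84 in females, so the arrays of the 2 sexes had not been forced to 1 distribution. No array repeated another, and the highest correlation between 2 arrays was 0.999. The number of arrays limits the precision of every value.

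A deposited table of adult tissues from the FlyAtlas project gives RMA-normalized values, per its description file, and these were taken as log2 values from their range. The 3 other deposited tables hold, per their description file, the association of each probe set with male fitness, with female fitness and with sexually antagonistic selection, taken by the authors from an earlier study of other flies. In these tables the t-statistic is a score whose sign has no stated direction, and the p-value and adjusted p-value come with it, per the file headers, with the adjustment method not given in the sources used here. The tables hold no comparison of the 5 strains, so they were used as lists of probe sets past an adjusted p of 0.05 and not as statistics of these arrays.

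Of 18952 probe sets, 183 control probe sets were left out and 18769 were tested. The platform annotation gave 1 gene symbol to 13647 of them, several to 402 and none to 4720, and genes were named only from probe sets with 1 symbol, of which 13544 were found in the RefSeq gene table of assembly Release 6 plus ISO1 MT. None of the 15 genes encoded in mitochondrial DNA had a named probe set, so their transcripts were not analysed here. No genome build was needed, and no coordinates are given; the RefSeq table served for names and for the genomic span of a gene.

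Tests used limma 3.58.1 in R 4.3.3, with tables and plots made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The introgressed line was the replicate: the 2 arrays of a line and sex were averaged, which cancels an additive batch effect, and a moderated F test compared the 5 strains over 10 line means within each sex. In the same fit, each strain was set against the mean of the other 4 strains; these contrasts share their lines and are not independent. The male minus female difference of each line was tested in the same way for its mean over strains and for a difference between strains. The lines of a strain were compared on the arrays with a batch term. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. With 2 lines a strain, p-values measure only the spread between introgressions of 1 strain. An exact permutation test of 2 lines against 8 allows 45 splits and no two-sided p below 0.0222. These exact p-values were not adjusted over the lists, strains and sexes.

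Whether the batch numbers pair arrays was checked on the deviations from the strain means. Same-numbered deviations of 2 strains correlated with r from -0.219 to 0.552 in males (median 0.186 over 10 pairs of strains) and from -0.0281 to 0.658 in females (median 0.455). The labels themselves call the number a batch, so arrays with the same number were taken as paired. An array-level fit with the batch as a block and the line as a random block was computed beside the line means. Results given with the batch as a block come from this whole fit, which uses arrays as units, while batch already cancels in a line mean. In males its estimated correlation within lines was -0.032, and it called 1256 probe sets with the batch block and 1288 without it. Batch 2 differed from batch 1 in 916 probe sets in males and 3785 in females by the array-level limma fit.

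Gene lists were written before the data were examined: mtDNA-encoded genes, OXPHOS complex I, complexes II and III, complex IV and complex V, TCA cycle, spermatogenesis and sperm, seminal fluid and accessory gland, eggshell and ovary, sex determination and dosage compensation, Y-linked, antimicrobial and immune effectors, heat shock and chaperones, detoxification, digestive enzymes, phototransduction and eye, muscle, neuronal, fat body and storage, mitochondrial ribosomal proteins and cytosolic ribosomal proteins. The first had no probe set, and the other 20 were tested. Tissue sets were the probe sets of the FlyAtlas table whose value was the highest of 17 adult tissues and at least 4 times the median over tissues. A list was tested by Fisher's exact test (two-sided) of its share of called probe sets, and by camera (limma) with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a test. Camera with an estimated correlation passed no list or set in any comparison, between the sexes included. A failure there does not show that a list was unshifted.

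Genes were named by a rule fixed in the same way. Only probe sets with 1 symbol were used, with 1 probe set per gene (the smallest p). The rule took the 20 largest ranges of strain means past the threshold within a sex, where both lines of the highest strain lay above both lines of the lowest, and the 10 largest ranges for the difference between sexes. It also took the 3 largest differences each way for a strain against the rest, with both lines on the same side, the 5 largest each way between the sexes, and up to 4 members with the smallest p of a list. Where nothing passed, the 3 smallest p were taken.

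The fits were tested on simulated data of 18769 probe sets, in which 100 were changed by 0.25 and 100 by 0.5 log2 units in 1 strain, drawn with the spread of the real line means. The male strain test recovered 49 of the smaller and 92 of the larger changes and called 10 unchanged probe sets, and the female strain test recovered 51 and 96 and called 7. For the sex difference test the changes were added to the male minus female difference of all 10 lines, with the spread of 1 sex. A real difference carries the spread of both sexes, so this setting was easier than the data. The sex difference test recovered 100 and 100 with the male spread, and 98 and 100 with the female spread.

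Alternatives fixed in advance were array-level fits with and without the batch block, each batch alone, no moderation, trend and robust moderation, a filter to the upper 60 percent of mean values, quantile normalization within sex, centring each array on its median, an adjusted p of 0.01, other tissue ratios, and leaving out each line, array or strain. After the data were seen, the signal of control transcripts near their 3 prime minus their 5 prime end (a sign of RNA quality) was added as a covariate, the accessory gland set was left out, the sex bias of calls was taken from centred arrays, and the strain contrasts and the shifts of lists in mysore males were computed under the other scalings.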

Results

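The arrays measured nuclear gene expression in whole adult flies that shared the w1118 nuclear background and carried 1 of 5 mitochondrial strains. The series asked how mitochondria affect nuclear gene expression. Each strain was represented by 2 independently introgressed lines, and each line by 2 arrays per sex, giving 20 male and 20 female arrays. All values are log2 values of 18769 probe sets, and strain values are means over 2 lines.

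In males, genes of the seminal fluid set brownsville and dahomey apart. Of 49 seminal fluid and accessory gland probe sets, 25 were lower in brownsville males and none higher, and 32 were higher in dahomey males and none lower, each against the mean of the other 4 strains. Adjusted over the list alone, the counts were 41 lower and 45 higher. Acp36DE, a seminal protein needed for sperm storage, was 0.34 ± 0.03 (SE, n = 2 lines) log2 units below the rest in brownsville, with a difference of -0.34 and a limma adjusted p of 0.000161. Acp53C14c, another accessory gland protein, had a difference of -0.39 ± 0.04 in brownsville and 0.41 ± 0.04 in dahomey (limma adjusted p 0.00017 and 0.000339). The serpin Acp76A had differences of -0.37 ± 0.03 and 0.42 ± 0.03 (limma adjusted p 0.000161 and 0.000315). The list mean differed from the rest by -0.21 in brownsville and by 0.25 in dahomey. These shifts were -0.23 and 0.30 in batch 1 and -0.18 and 0.20 in batch 2, and had the same sign in both lines of each strain and after quantile normalization or centring. An exact permutation test of the list mean of 2 lines against 8 gave p = 0.0444 for brownsville and p = 0.0222 for dahomey. Against all other probe sets, 32 of 49 (65.3%) passed the male strain test (odds ratio 60.8, Fisher's exact test, adjusted p = 3.35e-35). By camera the list was shifted in both strains with the preset correlation (adjusted p 1.11e-47 and 1.93e-39), and in neither with an estimated one (adjusted p = 0.0667 and 0.101 with an estimated correlation).

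The probe sets most enriched in the accessory gland, the male organ that makes most of the seminal fluid, gave the same picture over a wider set. In this set, 120 probe sets were lower and 1 higher in brownsville males, and 107 were higher and none lower in dahomey males, with mean shifts of -0.18 and 0.17. In all, 130 (51.0% of the set) passed the male strain test (odds ratio 40.5, Fisher's exact test, adjusted p = 6.47e-127). With the batch as a block on the arrays 148 passed, with an odds ratio of 21.7 (Fisher's exact test, adjusted p = 8.63e-106). By camera with an estimated correlation the shifts did not pass (adjusted p = 0.0508 and 0.187 with an estimated correlation). The ejaculatory duct set had 38 of 350 probe sets past the male strain test (odds ratio 3.92, Fisher's exact test, adjusted p = 2.94e-10), with 37 higher in dahomey and 16 lower and 3 higher in brownsville. With a set defined at 2 times the tissue median in place of 4, that odds ratio was 0.621 (adjusted p = 0.00326).

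**Figure D1:**
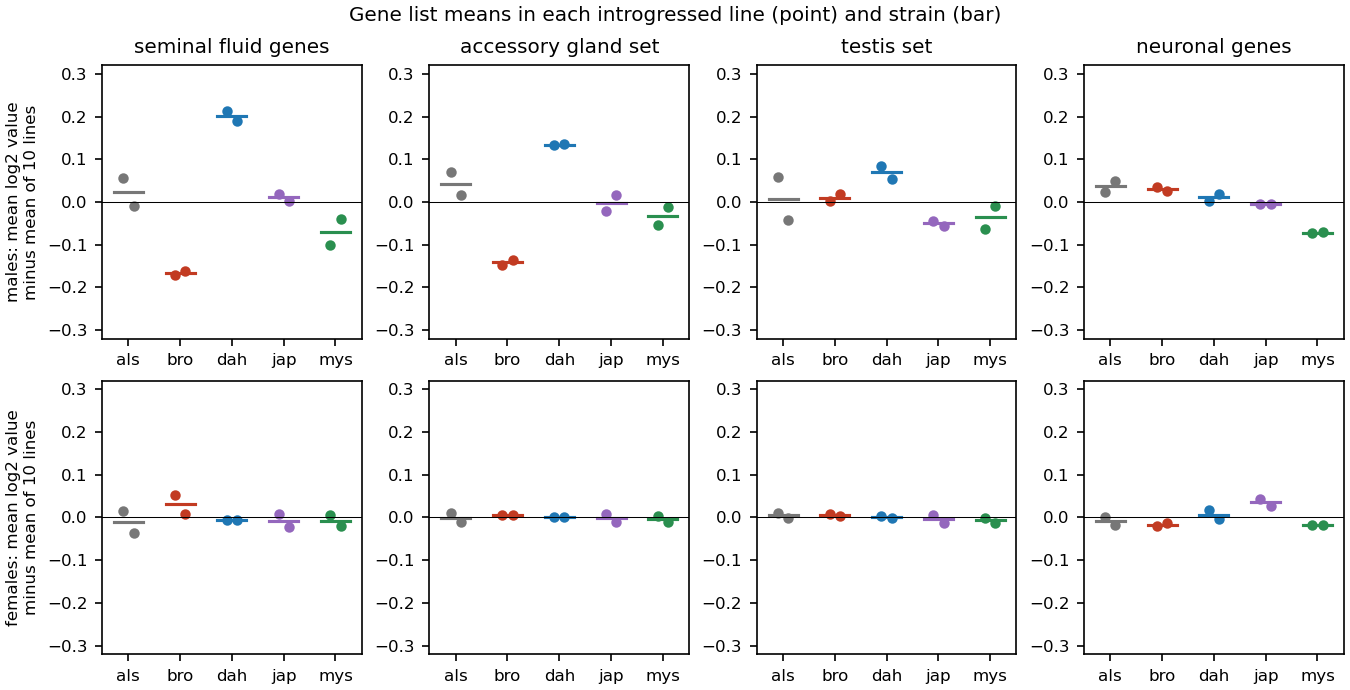
Mean log2 value of 4 gene groups in each introgressed line minus the mean of all 10 lines, for males (top) and females (bottom). Points are lines (mean of 2 arrays) and bars are strain means, with strains named by their first letters. In males the seminal fluid and accessory gland groups lay lowest in both brownsville lines and highest in both dahomey lines.

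Single genes named by the fixed rule showed the same strains at the ends. CG17472 was highest in dahomey males (12.11 ± 0.05, SD, n = 2 lines) and lowest in brownsville males (11.25 ± 0.01), a range of 0.86 log2 units or 1.82-fold (limma adjusted p 0.000114). CG12828, CG13639, CG34130, CG9997, lectin-29Ca, antr, Acp53C14c and lectin-30A also had dahomey highest and brownsville lowest, with ranges of 0.75, 0.73, 0.70, 0.66, 0.66, 0.65, 0.64 and 0.63. Among them, antr and CG9997 belong to the proteins that keep sex peptide acting in mated females, and lectin-29Ca and lectin-30A are C-type lectins. Dahomey males also had the highest and brownsville males the lowest values of CG11911, CG17571 and CG1648, with ranges of 0.73, 0.69 and 0.66.

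Some brownsville differences stood apart from every other strain. The secreted glial glycoprotein gene ana was at 7.91 ± 0.02 (SD, n = 2 lines) in brownsville males and between 8.69 and 8.76 in the other strains, with a difference from the rest of -0.80 ± 0.05 (SE; limma adjusted p 7.63e-06). CG42521 and CG10175 were also lower in brownsville males, with differences of -0.71 ± 0.05 and -0.67 ± 0.05 (limma adjusted p 2.78e-05 and 5.07e-05). CG4267 was higher, at 7.04 ± 0.03 (SD) against a mean of 6.35 in the rest, a difference of 0.70 ± 0.04 (SE; limma adjusted p 7.57e-06). CG34040 and CG3534 were higher in brownsville males by 0.72 ± 0.14 and 0.46 ± 0.07 (limma adjusted p 0.0184 and 0.006). CG34040 had the widest range of strain means, 0.97 log2 units, with its lowest value in alstonville. Dahomey males had few lower genes, 6 probe sets in all. Of the named ones, Strn-Mlck and CG42700 had differences of -0.19 and -0.16. The third was CG4267 (-0.21), for which the high values of brownsville lay in the rest: dahomey was at 6.32 and japan at 6.33.

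**Figure D2:**
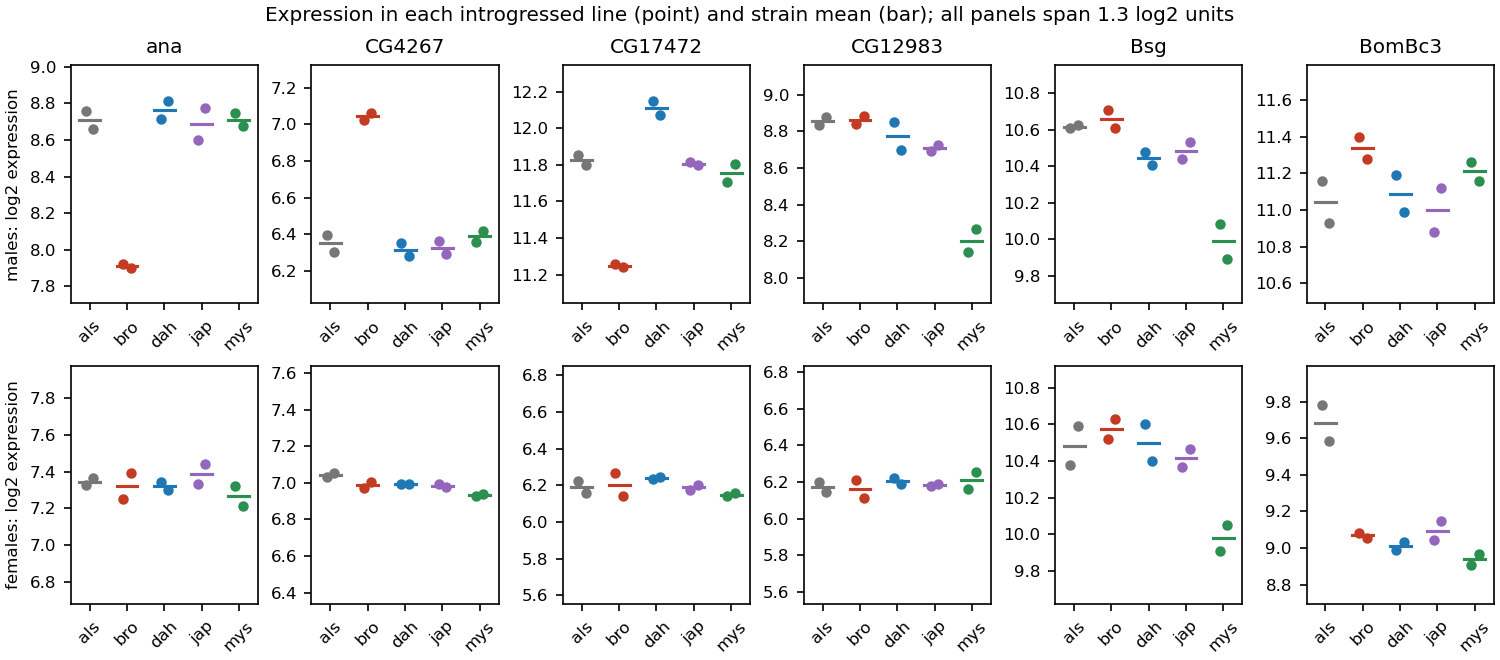
Expression (log2) of 6 genes in males (top) and females (bottom), with 1 point per introgressed line (mean of 2 arrays) and a bar at each strain mean; every panel spans the same number of log2 units. In males ana, CG4267 and CG17472 set brownsville apart and CG12983 set mysore apart, Bsg was lowest in mysore in both sexes, and BomBc3 was highest in alstonville females.

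Digestive enzyme genes moved in both directions in brownsville males, with 5 of 40 probe sets higher and 5 lower. The maltase Mal-A6, the alpha-glucosidase tobi and the amylase relative Amyrel were higher by 0.37, 0.41 and 0.35 log2 units, and the serine protease yip7 had a difference of -0.30 (limma adjusted p from 0.00286 to 0.00888). In all, 9 of the 40 passed the male strain test (odds ratio 9.02, Fisher's exact test, adjusted p = 3.36e-05), and 13 passed adjusted over the list alone. The list mean in brownsville was -0.10 from the rest in batch 1 and 0.13 in batch 2. In the array-level fit with the batch as a block the list no longer passed (odds ratio 2.97, Fisher's exact test, adjusted p = 0.105). That fit called 6.67% of the other probe sets, in place of 3.12%. The midgut set had 40 of 608 past the test (odds ratio 2.24, Fisher's exact test, adjusted p = 6.2e-05), and with the batch as a block its odds ratio was 0.954 (adjusted p = 0.869).

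Males with mysore mitochondria had lower values of neuronal genes. Of 50 neuronal probe sets, 13 were lower in mysore males and none higher, and 17 were lower adjusted over the list alone. They included futsch, a microtubule-associated protein of axons (-0.36 ± 0.03, SE, n = 2 lines), nSyb, the neuronal synaptobrevin (-0.45 ± 0.06), elav, an RNA-binding protein of neurons (-0.33 ± 0.04), and the potassium channel gene Sh (-0.22 ± 0.03), with limma adjusted p of 0.000208, 0.00157, 0.00157 and 0.00314. The list mean differed by -0.09 from the rest, by -0.13 in batch 1 and -0.05 in batch 2, and by -0.07 and -0.06 after quantile normalization and centring (exact permutation test over lines, p = 0.0222). In the male strain test 9 of 50 passed (odds ratio 6.81, Fisher's exact test, adjusted p = 0.000155), and with the batch as a block on the arrays the list did not (odds ratio 1.55, adjusted p = 0.756). By camera the list was lower in mysore (adjusted p 2.23e-06), but not with an estimated correlation (adjusted p = 0.109 with an estimated correlation). The sets of nervous tissue were lower as well: 89 of 991 brain, 48 of 528 thoracicoabdominal ganglion and 19 of 257 eye probe sets were lower in mysore males, and none were higher. For these sets camera gave adjusted p = 0.402, 0.772 and 0.772 with an estimated correlation. The array medians of mysore males were among the lowest of the male arrays, between 7.30 and 7.31, so small shifts of whole sets depended on scaling. The neuronal list and the brain set (-0.06 as deposited, -0.03 centred, -0.04 after quantile normalization) kept an exact permutation p of 0.0222 under each scaling. This is the smallest p the test allows, unadjusted over lists, so it does not show that the size of a shift was stable. The eye and ganglion sets were at -0.05 each as deposited (exact permutation p = 0.0222) and at -0.02 each centred (exact permutation p = 0.289 and 0.0889). The crop, salivary gland, mated spermatheca, hindgut and fat body sets also had an exact permutation p of 0.0222 as deposited, and of 0.533 or more under the other scalings. The fat body list went from -0.10 to -0.07 centred and -0.04 after quantile normalization (exact permutation p = 0.0222, 0.0444 and 0.178). The lists of muscle genes and cytosolic ribosomal proteins went from -0.10 each to -0.04 and -0.02 (exact permutation p = 0.111 each as deposited, 0.644 and 0.244 after quantile normalization). The immune effector list was higher in mysore males, by 0.10 as deposited and 0.13 centred or quantile normalized (exact permutation p = 0.0222 under each), with 2 of 21 probe sets past the threshold adjusted over the list alone. By camera it was at adjusted p = 0.0677 with an estimated correlation. In the male strain test 64 of the brain set, 26 of the ganglion set and 18 of the eye set passed (Fisher's exact test, adjusted p 3.32e-07, 0.0648 and 0.00567). With the batch as a block the brain and eye sets did not pass (adjusted p = 0.573 and 0.311).

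Other genes lower in mysore males were CG12983 (-0.60 ± 0.04, SE), Bsg, which encodes the membrane glycoprotein basigin (-0.56 ± 0.05), and CG42540 (-0.55 ± 0.05), with limma adjusted p of 0.000186, 0.000208 and 0.000372. In the muscle list 4 of 42 probe sets were lower, among them sls, the titin homologue (-0.39), and Msp300 (-0.26). In the phototransduction list 3 of 33 were lower, including rdgA, an eye diacylglycerol kinase (-0.34), and rdgB (-0.33). Neither list passed the male strain test as a group (Fisher's exact test, adjusted p = 0.214 and 0.341). Few probe sets were higher in mysore males; the named genes were CG7542, Cpr66Cb and Prx6c, with differences of 0.30, 0.17 and 0.17.

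**Figure D3:**
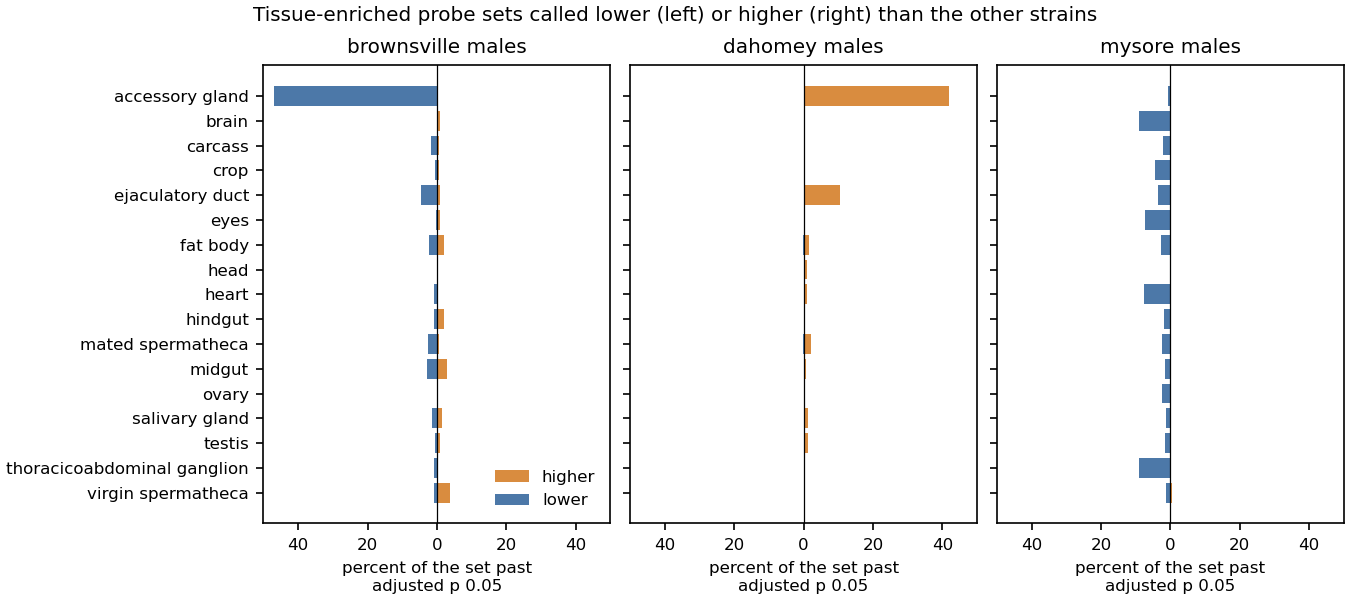
Percent of each tissue-enriched set of probe sets called lower (left of 0) or higher (right of 0) in brownsville, dahomey and mysore males than in the mean of the other 4 strains (limma on line means). Accessory gland probe sets stood out as lower in brownsville and higher in dahomey, and brain and ganglion probe sets as lower in mysore.

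The lists of genes whose products work in mitochondria held no call of the male strain test. In that limma test, 0 of 33 probe sets of complex I, 0 of 16 of complexes II and III, 0 of 16 of complex IV, 0 of 18 of complex V, 0 of 19 of the TCA cycle and 0 of 71 mitochondrial ribosomal proteins passed. Adjusted over the list alone, 2 passed for complexes II and III and 2 for complex IV. With 3.16% of all probe sets called, lists this small would hold few calls, and none passed Fisher's exact test (lowest adjusted p = 0.585). A count of 0 therefore does not show that a list was unshifted. The complex I mean was -0.10 from the rest in brownsville males, by -0.18 in batch 1 and -0.03 in batch 2. In alstonville, dahomey, japan and mysore males it was 0.08, 0.05, 0.03 and -0.05. Single strain contrasts called 1 probe set of complexes II and III lower in brownsville and 1 lower in mysore, 1 of the TCA cycle higher in brownsville, and 1 of complex IV, in COX7AL, higher in dahomey (0.21 ± 0.04, SE; limma adjusted p 0.0456). Also with 0 calls in the strain test were the lists of cytosolic ribosomal proteins, antimicrobial and immune effectors, sex determination and dosage compensation, and Y-linked genes. The other lists had 4 of 76 (detoxification), 1 of 59 (eggshell and ovary), 1 of 31 (fat body), 1 of 23 (heat shock) and 2 of 65 (spermatogenesis), none past Fisher's exact test. The heat shock list passed with the batch as a block on the arrays, with 6 of 23 (odds ratio 4.94, Fisher's exact test, adjusted p = 0.0333).

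Transcripts of the gonads took less than their share of male calls. The testis set had 49 of 2152 past the male strain test (odds ratio 0.688) and the ovary set 32 of 1515 (odds ratio 0.642), each with Fisher's exact test and an adjusted p of 0.034. Neither passed at 10 times the tissue median, with similar odds ratios over fewer probe sets (0.770 over 1797 and 0.703 over 531, adjusted p = 0.194 and 0.393) or with the batch as a block on the arrays (odds ratios 0.909 and 0.816, adjusted p = 0.475 and 0.201). The mean of the testis set was 0.09 log2 units above the rest in dahomey males, by 0.16 in batch 1 and by 0.01 in batch 2. It was 0.04 above after quantile normalization and 0.07 centred. The remaining tissue sets did not pass: 5 of 191 for carcass, 7 of 208 for crop, 17 of 354 for fat body, 0 of 95 for head, 5 of 119 for heart, 6 of 259 for hindgut, 18 of 370 for mated spermatheca, 2 of 75 for salivary gland and 20 of 542 for virgin spermatheca. The sets of fat body, mated spermatheca and salivary gland passed with the batch as a block on the arrays (odds ratios 1.65, 1.81 and 2.67, Fisher's exact test, adjusted p = 0.0236, 0.00407 and 0.0168).

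Counted over all probe sets, the limma moderated F test called 593 of 18769 (3.16%) in males, covering 495 named genes, and 4069 had an unadjusted p under 0.05. The strain means of a called probe set spanned a median of 0.32 log2 units, 81 of them at least 0.5 and none 1 or more. Against the rest, 120 probe sets were higher and 213 lower in brownsville, 214 higher and 6 lower in dahomey, and 11 higher and 444 lower in mysore. In alstonville and japan the limma contrast called 0, with 1612 and 1995 at an unadjusted p under 0.05. The smallest p-values there belonged to CG12766, meep and Tob (limma adjusted p 0.321) and to CG12506, trol and Hph (limma adjusted p 0.464). With the batch as a block on the arrays, 1256 probe sets were called over the strains, 1070 in dahomey (951 higher) and 2 in alstonville, and 508 of the 593 were among the 1256. An unmoderated F test on the line means called 0. Batch 1 alone called 2253 and batch 2 alone 30. Without line bro1, bro2, dah1, dah2, mys1 or mys2 the strain test called 203, 219, 259, 282, 361 or 344, and without jap2 1417. In the contrasts, brownsville had 66, 73, 219 or 634 without bro1, bro2, dah2 or jap2, and mysore 121, 291, 293 or 709 without mys2, dah1, bro1 or jap1, with a count between the first and the second of these without mys1. Dahomey had 17, 38, 113, 116, 454, 476 or 1083 without dah1, dah2, bro2, bro1, jap2, mys2 or als1, and 55 with the RNA quality signal of the arrays as a covariate. With quantile normalization dahomey had 71 calls (67 higher) and mysore 260 (233 lower), and on centred arrays mysore had 295 (252 lower). Without jap2, 148 were called in japan and 1 in alstonville, and without jap1 2 in alstonville.

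**Figure D4:**
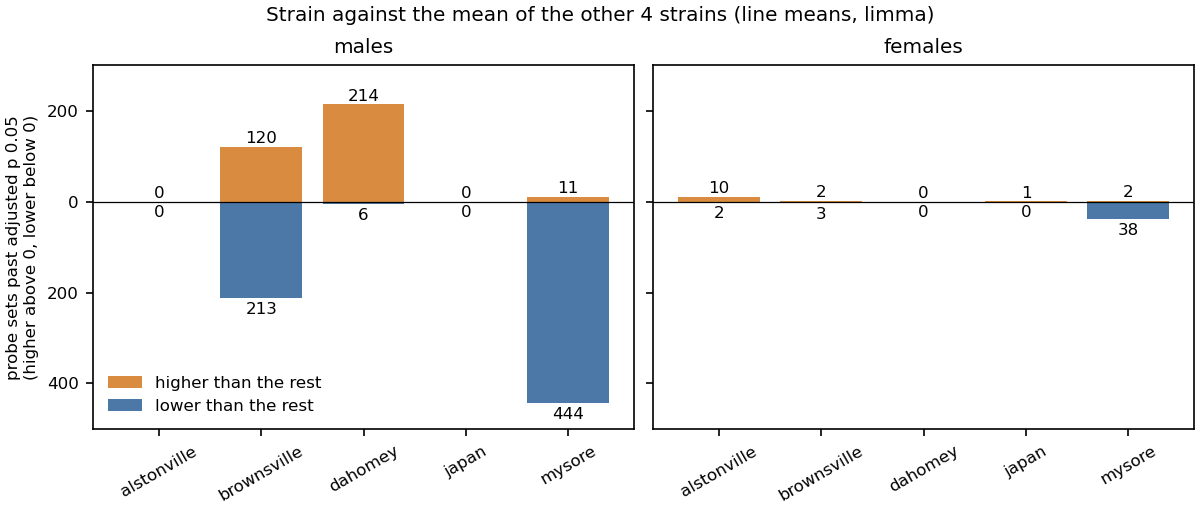
Number of probe sets past a limma adjusted p of 0.05 in each strain against the mean of the other 4 strains, in males (left) and females (right); bars above 0 count higher and bars below 0 count lower probe sets. Males gave 333, 220 and 455 calls in brownsville, dahomey and mysore, and females 40 in mysore and at most 12 in the other strains.

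In females, few genes differed between strains. The gene with the widest range was BomBc3, a bomanin (a family of immune-induced secreted peptides), at 9.68 ± 0.14 (SD, n = 2 lines) in alstonville and between 8.94 and 9.10 in the other strains (range 0.74 ± 0.06, SE; limma adjusted p 0.000846). Fbp2, a fat body protein, was highest in brownsville females (range 0.70 from dahomey), CG5773 was lowest in brownsville and highest in japan (0.70), and Bsg was lowest in mysore (0.59), as in males. CG16772, wcy, Ser8 (a serine protease) and NiPp1 (an inhibitor of protein phosphatase 1) had ranges of 0.51, 0.46, 0.41 and 0.32, with limma adjusted p from 0.0257 to 0.0468.

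Calls in females differed in number between strains. In alstonville 10 probe sets were higher and 2 lower: BomBc3, CG16772 and Sid were higher by 0.65, 0.48 and 0.32, and CG12057 and NiPp1 had differences of -0.61 and -0.27. The alstonville group also held the antimicrobial peptide gene Mtk (0.31) and a second bomanin, BomS5 (0.31), which are named here after their values were seen. In brownsville Fbp2 and Ser8 were higher by 0.59 and 0.31, CG5773 had a difference of -0.48, and the other 2 probe sets had no gene symbol. In mysore 38 were lower and 2 higher, with Nxf3, Bsg and Glut4EF at -0.54, -0.51 and -0.44 and pAbp and retm at 0.25 and 0.20. Mysore females also had the highest RNA quality signal (3 prime minus 5 prime), 1.69 against 1.52 in dahomey to 1.63 in brownsville. The mysore contrast was not refitted with this signal as a covariate. The female test over all strains was, and it called 81 probe sets in place of 10. In japan 1 probe set without a gene symbol was higher. In dahomey the limma contrast called 0, with 826 at an unadjusted p under 0.05, and Uhg4, CG31300 and vri had the smallest p (limma adjusted p 0.93).

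The female strain test called 10 probe sets, 8 of them in named genes, with 1453 at an unadjusted p under 0.05. No gene list or tissue set passed Fisher's exact test there; digestive enzymes (1 of 40) and fat body genes (1 of 31) came nearest (adjusted p = 0.211 for each). With only 10 calls, Fisher's exact test does not show that the lists were unshifted. Adjusted over the list alone, 14 of 42 muscle probe sets passed. The muscle list mean was 0.13 above the rest in japan females (0.13 and 0.14 in batches 1 and 2). It was -0.11 from the rest in brownsville females, in each batch. In alstonville, dahomey and mysore it was 0.00, -0.01 and -0.01, but alstonville was at 0.20 in batch 1 and -0.19 in batch 2. No seminal fluid or accessory gland probe set was called. With the batch as a block on the arrays the test called 1, and the contrasts called 1 in alstonville (lower, with none of the higher calls kept), 0 in brownsville (1121 on the line means at an unadjusted p under 0.05) and 0 in japan. Without line dah1 or dah2 it called 100 or 104, without bro2 16, and without als2, bro1, jap1, jap2 or mys1 2, 3, 4, 3 or 1. For mysore, the 40 became 0, 9, 9, 10, 14, 25 or 77 without mys1, mys2, jap1, bro2, als2, jap2 or dah2, and 3 with centring or with quantile normalization. Either scaling gave 5 calls in alstonville, and brownsville had 3 centred and 0 after quantile normalization.

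The strains shifted some genes in 1 sex more than in the other. In the test of that difference itself, 96 probe sets passed (1587 at an unadjusted p under 0.05), and 66 of them came from the accessory gland set (Fisher's exact test, adjusted p = 5.72e-102) and 20 from the 49 of the seminal fluid list (adjusted p = 9.13e-33), of which 43 passed adjusted over the list alone. Females had little signal for these transcripts: the seminal fluid list averaged 6.63 in females and 11.52 in males, and the accessory gland set 6.66 and 8.78. A strain difference of these genes in males therefore enters this test almost unchanged, and the enrichment restates the male result. The ejaculatory duct set had 7 of 350 (adjusted p = 0.0181), and no other list or set passed. For CG17472 the male minus female difference was 5.87 in dahomey and 5.05 in brownsville, a gap of 0.82 ± 0.06 (SE, n = 2 lines; limma adjusted p 0.000623). For ana, CG4267, CG12828, CG13639, CG12983, antr, CG10175 and CG34130 the gap was between 0.67 and 0.85, and the F test of the strains was past the threshold in males and not in females. BomBc3 was the reverse: between mysore and alstonville its values differed by 0.74 in females, with the F test past the threshold there (limma adjusted p 0.000846) and not in males (0.165). Of the 96, 89 were also male calls and 3 female calls, both of which share arrays with this test. With the batch as a block on the arrays 161 passed. Without bro1, bro2, dah1 or dah2 it was 12, 21, 29 or 36.

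Across all probe sets, the 2 lines of a strain moved together in males for 3 strains. The correlation between the lines over probe sets was 0.550 in brownsville, 0.642 in dahomey and 0.319 in mysore, and -0.0433 in alstonville and -0.129 in japan. In females it was -0.115 in alstonville, 0.202 in brownsville, -0.103 in dahomey, 0.329 in japan and 0.0344 in mysore. The sides of each correlation share no array, and probe sets are not independent replicates. No probe set differed between the lines of a strain in the limma array fit, which called 0 in each sex and gave 749 in males and 529 in females at an unadjusted p under 0.05. The smallest p-values belonged to mnd, cbt and CG31091 in males (limma adjusted p 0.547) and to otk2, CG42807 and CG5849 in females (limma adjusted p 0.954).

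Strain differences in males and females were weakly related over probe sets. The correlation of a strain's male and female differences was 0.339 in mysore, 0.238 in japan, 0.215 in brownsville, 0.212 in dahomey and 0.0622 in alstonville. Setting line 1 of males against line 2 of females, so that no line was on both sides, gave a median over strains of 0.186, and the reverse gave 0.180. These values changed sign between strains, with the lowest at -0.0480 in dahomey and, in the reverse, -0.125 in japan. Of the 455 mysore calls in males, 91.6% had the same direction in females, compared with 60.9% of the other probe sets, of which 62.8% were lower in mysore females. In brownsville and dahomey it was 60.4% and 62.3% of the calls, compared with 55.3% and 60.8% of the others. In mysore, 23 probe sets were called in the same direction in both, Bsg, Glut4EF and nSyb among them.

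Between the sexes themselves, transcripts of the male reproductive tract and of the ovary had the largest measured differences. The genes of the ejaculatory bulb proteins EbpII and Ebp had means of 14.76 ± 0.11 and 14.65 ± 0.12 in males (SD, n = 10 lines), and Acp53C14a, Acp53Ea and Mst57Da 14.19, 13.90 and 14.14. Their female means, between 5.99 and 6.45, were near the lowest value of the arrays (5.65), so the differences of 7.85 to 8.48 log2 units were lower bounds and did not rank these genes. The eggshell genes Cp38, Cp36 and Cp19 were lower in males, with differences of -7.27 ± 0.09, -7.17 ± 0.13 and -6.98 ± 0.12 (SE, n = 10 lines), as were the yolk protein genes Yp2, Yp1 and Yp3 (-6.76, -6.71 and -6.49). All of these lay in the same direction in 10 of 10 lines, with limma adjusted p of at most 1.06e-16. Seminal fluid genes averaged 4.90 above females, sperm genes 2.80 above and eggshell and ovary genes -3.58 from females. In the testis set 1938 of 2152 probe sets were higher in males, and in the ovary set 1513 of 1515 were lower. The Y-linked genes kl-2, kl-3 and kl-5 had values near the floor in both sexes. Their differences of 0.06 to 0.47 were smaller than the 0.54 between the array medians of the sexes, so they turn to lower in males on centred arrays, and kl-5 was higher in 8 of 10 lines. Pp1-Y2 was higher in males by 1.27.

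Respiratory chain genes averaged higher in males, by 0.87 in complex I, 1.46 in complexes II and III, 2.14 in complex IV and 0.88 in complex V, and TCA cycle genes by 0.92. The largest differences were in duplicate genes of the usual subunits, such as COX4L (5.17), COX7AL (4.51), SdhBL (3.84) and ATPsynGL (3.43). Mitochondrial ribosomal proteins went the other way, with 71 of 71 probe sets lower in males and a mean difference of -1.32. After each array was centred on its median these means were 0.34, 0.93, 1.60, 0.35, 0.39 and -1.86, so no direction of a mean turned. Centred, the probe sets past the threshold were 23 higher and 6 lower in complex I, 14 and 2 in complexes II and III, 12 and 2 in complex IV, 10 and 6 in complex V and 11 and 5 in the TCA cycle. With an estimated correlation camera passed 0 of the gene lists between the sexes, these included. It also did not pass the seminal fluid list, which was 4.90 above females and higher in 10 of 10 lines. Muscle genes averaged 1.12 above females (0.58 centred), detoxification genes 0.71 (0.18), fat body genes 0.70 (0.17), phototransduction genes 0.70 (0.16), neuronal genes 0.63 (0.10), heat shock genes 0.60 (0.06) and Y-linked genes 0.55 (0.01). Sex determination genes averaged -1.01 (-1.55 centred) and cytosolic ribosomal proteins -0.40 (-0.94). Digestive enzymes and immune effectors averaged 0.41 and 0.35 above females and turned to -0.12 and -0.19 after centring. The tissue sets of brain, fat body, heart, hindgut, midgut, salivary gland, thoracicoabdominal ganglion and virgin spermatheca likewise turned from higher to lower in males. After centring, the means of the accessory gland, carcass and head sets were 1.58, 0.59 and 0.37 above females and that of mated spermatheca was at -0.87. The crop and eye sets were at 0.06 and 0.00, and the ejaculatory duct set at 0.27 with more probe sets lower (180) than higher.

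Over all probe sets, 9371 were higher and 6908 lower in males, 16279 in all of 18769. The array medians of males lay 0.54 log2 units above those of females as deposited. With every array centred on its median, 4110 were higher and 14245 lower, so the share of calls higher in males was 57.6% as deposited and 22.4% centred. By camera 15 of 20 gene lists and 17 of 17 tissue sets differed between the sexes with the preset correlation, and 0 of each with an estimated one.

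Probe sets that differed between strains in males were more often higher in males than in females. Of the 593, 410 (69.1%) were higher in males, compared with 49.3% of other probe sets (odds ratio 2.30, Fisher's exact test, adjusted p = 7.09e-21). The share was 84.5% among those lower in brownsville, 81.8% among those higher in dahomey and 57.0% among those lower in mysore. With every array centred on its median, the shares were 57.2% of the 593 compared with 20.7% of the others (odds ratio 5.10, Fisher's exact test, p = 3.33e-80), 74.6% for brownsville, 76.6% for dahomey and 39.4% for mysore. This scaling was added after the data were seen. With calls from the arrays and the batch as a block, the odds ratio was 1.06 (Fisher's exact test, p = 0.365).

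Male strain calls overlapped with genes tied to male fitness in other flies. In the authors' deposited table for male fitness, 74 of the 593 male calls (12.5%) were past an adjusted p of 0.05, compared with 4.35% of other probe sets (odds ratio 3.13, Fisher's exact test, adjusted p = 2.8e-14). In the authors' deposited table for sexually antagonistic selection it was 64 calls (10.8%) compared with 7.77% (odds ratio 1.44, adjusted p = 0.0308), and in the authors' deposited table for female fitness 15 calls (2.53%) compared with 3.41% (odds ratio 0.736, adjusted p = 0.595). Without the accessory gland set, the odds ratio for the authors' deposited table of male fitness was 1.67 (Fisher's exact test, p = 0.0103).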

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

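The 3 patterns were picked after the main results were seen; 3 tests, of transcripts nearly limited to the gland, of probes that respond unequally and of the spread between lines, were chosen after their results or closely related ones were seen, and the predictions of the others were written before they were run.

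In males, genes of the accessory gland were lower in brownsville and higher in dahomey. Array scaling might give such a shift. Probe sets matched for level moved by 0.229 of the shift of the set in dahomey and by -0.00878 of it in brownsville. This excludes scaling as the whole cause, but part of the dahomey shift depended on it. The set mean in dahomey was 0.17 as deposited and 0.13 after quantile normalization, and in brownsville -0.18 and -0.17. RNA quality could contribute. With the 3 prime minus 5 prime signal as a covariate the brownsville shift was -0.192 ± 0.055 (SE), against -0.177 without it. The dahomey shift was 0.218 ± 0.054 (SE), against 0.168 without it, so a difference in this signal is excluded as the cause too. Over all probe sets, the dahomey calls fell from 220 to 55 with the covariate. A different share of gland tissue would move all transcripts of the gland alike if all probes responded alike, but the dahomey minus brownsville differences of 88 strongly enriched probe sets varied 7.53 times as much as their error (bootstrap interval 4.61 to 11.3), and those of 32 nearly limited to the gland 8.01 times (4.77 to 11.7). With a response of its own for each probe set, the variance between strains left was 1.72 (1.20 to 2.60) and 1.56 (1.07 to 2.18) times the error, so a changed share cannot be told apart from changes of single genes or of cell proportions within the gland, and 87 of the 88 differences had the same sign.

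In mysore males, neuronal genes were lower. RNA quality might lower long transcripts. With the signal as a covariate the shift was -0.0907 ± 0.016 (SE), against -0.0904 without it. Mysore males had a mean signal of 1.78, between alstonville (1.70) and dahomey (1.82), so the covariate had little to remove. A difference in this signal is excluded as the cause. An effect on long transcripts that the signal does not show was not tested. Gene length could account for part of the shift: 1.19 percent of random lists matched for genomic span had a median as low, with a typical matched median of -0.03 against -0.06. The random lists drew each probe set on its own, whereas the 50 neuronal probe sets came from 30 genes. Their medians may therefore spread too little, and this test cannot exclude length as the whole cause. A lower share of nervous tissue stays open, because the 520 probe sets most enriched in brain had a median shift of -0.0586 ± 0.004, against -0.02 for all probe sets. Part of that shift depended on scaling: it was -0.03 on centred arrays and -0.04 after quantile normalization, with 68.7% and 77.1% of these probe sets below 0 in place of 84.2%.

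Males had more strain calls than females. A larger spread between female lines could give this, but the median residual SD of females over that of males was 1.00. Signals near the floor in females might also do so, yet over the male median level in both sexes 316 male and 9 female calls remained. Genes expressed mainly in males may add calls, yet among probe sets not higher in males 183 male and 4 female calls remained. Signals near the floor and genes expressed mainly in males are each excluded as the only cause. The median spread cannot show a larger spread held in a few lines or probe sets. Without dahomey the strain test called 118 probe sets in females and 284 in males. With the RNA quality covariate it called 81 in females and 475 in males. Spread within 1 strain and RNA quality are therefore not excluded as contributors, and a response to mitochondria that is stronger in males stays open.

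The 10 lines were also paired into strains in other ways, 100 pairings counting the true one, and a contrast was set against the pair with the most calls in each other pairing. By this count chance was unlikely for the male strain calls (593 real, 353 highest other, 1 of 100 as high) and the difference between sexes (96, 86 and 1). It was also unlikely for brownsville males (333, 371 and 2) and mysore males (455, 371 and 1). The count allows no share below 1 of 100, and the shares were not adjusted over the results tested. The pairing with 353 calls and a pair of 371 kept 2 true pairs, so these values are not a pure level of chance. Chance cannot be excluded by this count for dahomey males (220 and 371; 7). Of the 57 pairings that kept no true pair, none had a male pair with as many calls as dahomey, and the highest had 98. Chance cannot be excluded for the female strain calls (10 and 109; 13) or for alstonville (12 and 108; 24), brownsville (5 and 108; 39) and mysore females (40 and 108; 15). Some other female pairings called several times as many probe sets as the true one, and whether the lines hold a structure other than the strain was not tested. For the sex difference, with signs exchanged over the lines, chance was unlikely (16279 real, 13411 highest other, 1 of 100 as high).

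Of 205 groups of 4 arrays of a named gene, 10 had an array far from the other 3 by Dixon's test, which by chance picks out about 1 in 20 groups (10.2 expected). In males these were CG42521 in bro1 batch 2 (7.07, nearest 6.97), CG13639 in dah2 batch 2 (9.88, nearest 9.99), CG10175 in als2 batch 2 (8.10, nearest 7.96) and Acp53C14c in mys1 batch 2 (11.13, nearest 11.25). Also in males were CG42700 in bro2 batch 1 (7.26, nearest 7.30) and Cpr66Cb in jap2 batch 1 (7.09, nearest 6.99). In females these were Fbp2 in als1 batch 1 (7.69), wcy in dah2 batch 2 (10.36, nearest 10.51), retm in als1 batch 2 (8.69, nearest 8.75) and Nxf3 in dah2 batch 2 (8.31, nearest 8.88).

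The effect of the strain differed between the sexes, by the limma test of that difference itself, in 89 named genes. The 10 with the largest ranges are given here. The male minus female difference differed by 0.91 for BomBc3 (mysore against alstonville), 0.85 for ana (mysore against brownsville), 0.82 for CG17472, 0.81 for CG12828, 0.75 for CG13639, 0.70 for antr and 0.67 for CG34130 (dahomey against brownsville). It differed by 0.75 for CG4267 (brownsville against alstonville), 0.71 for CG12983 (brownsville against mysore) and 0.68 for CG10175 (alstonville against brownsville).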

How the results depend on the processing

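The RNA quality covariate, leaving out the accessory gland set, the sex bias on centred arrays and the strain contrasts under other scalings were chosen after the results were seen; all other alternatives were fixed before. Outside single arrays and lines, 80 alternatives stayed the same: a count within 1.5 times, or a list test on its side of the threshold. For counts this took no account of direction. On centred arrays the sex difference stayed within it (18355 calls against 16279), although calls higher in males went from 9371 to 4110. A further 63 moved beyond these bounds, 9 lost the threshold and 4 turned the direction, and the cause was not tested. The sex difference kept between 15932 and 16164 calls without any line and 6511 at 2-fold or more, and line calls stayed at 0. Signal near the background limits small changes, and a strain left with 1 line was assumed to vary like the others.

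With the line random and the replicate block on the arrays, calls were 1256 over strains in males (alstonville 2, dahomey 1070), 1 in females (alstonville 1, brownsville 0, japan 0) and 161 for the difference between sexes. In this array-level fit the odds ratios of male calls were 2.97 (digestive), 1.55 (neuronal), 1.38 (eyes), 0.816 (ovary), 0.909 (testis) and 1.06 (male bias). The midgut turned to 0.954, and the brain set also lost the threshold. In the same fit the heat shock list and the fat body, mated spermatheca and salivary gland sets passed. Without the replicate block, males had 1288 and females 0. With arrays as independent samples, counts were 1040, 1 and 170 (males, females, difference between sexes).

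In the same order, counts were 2253, 0 and 15 in batch 1, 30, 5 and 2 in batch 2, and 0, 0 and 0 unmoderated. With trend and robust moderation females had 100 and the difference 248. With the upper 60 percent, they had 1 and 61, and alstonville females 5. Quantile normalization gave 376, 4 and 51, an adjusted p of 0.01 gave 208, 1 and 28, and centring gave females 1. Against the rest, quantile normalization gave 71 in dahomey and 260 in mysore males, and 5, 0, 0 and 3 in alstonville, brownsville, japan and mysore females. Centring gave 295 in mysore males, and 5, 3 and 3 in alstonville, brownsville and mysore females. Without brownsville counts were 137, 2 and 2, and without dahomey 284, 118 and 16. Males and females had 1117 and 3 without japan, and 232 and 5 without mysore. With the RNA quality covariate females had 81 and dahomey males 55; without the accessory gland set males had 386.

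Leaving out 1 line gave 203 to 1417 calls in males (bro1, jap2), 1 to 104 in females (mys1, dah2) and 12 to 99 for the difference (bro1, jap2). Leaving out 1 array gave 238 to 1027 (mys1 batch 1, jap2 batch 2), 0 to 82 and 45 to 133. For males against the rest, lines gave 0 to 2 (alstonville), 66 to 634 (brownsville), 17 to 1083 (dahomey), 0 to 148 (japan) and 121 to 709 (mysore). For females they gave 3 to 17, 0 to 55, 0 to 1, 0 to 128 and 0 to 77.

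The median correlation of lines in females turned to -0.0308 with the upper 60 percent and -0.0329 with quantile normalization. With an estimated correlation, camera passed 0 in place of 82 gene lists and 62 tissue sets over the strain contrasts, and 0 in place of 15 and 17 between the sexes. At 2 times the tissue median 12 sets passed Fisher's exact test in place of 7, and the ejaculatory duct turned to an odds ratio of 0.621. At 10 times, the ovary had 0.703 and the testis 0.770.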

Other observations

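The values and tests in this part were chosen after the results were seen.

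Genes lower in mysore males were mostly long genes. Of 372 mysore-lower male calls with a known genomic span, 262 lay in the longest of 4 nearly equal groups of probe sets by gene span (odds ratio 7.66, interval 6.09 to 9.69, Fisher's exact test, p = 6.11e-78). Leaving out the brain, ganglion, eye and head sets, it was 149 of 240 (odds ratio 6.35, interval 4.84 to 8.37). Fisher's exact test took each probe set as independent, although several can share a gene and all rest on the same 2 mysore lines. The p-value and intervals may therefore overstate the evidence. From the shortest to the longest group, 0.325%, 0.560%, 2.36% and 7.74% of probe sets were lower in mysore males, and 0, 3, 9 and 21 probe sets in mysore females. Brownsville went the other way, with 3.01%, 1.98%, 0.798% and 0.148% lower in males. In dahomey males 120, 49, 21 and 10 were higher. The accessory gland set held many of these brownsville and dahomey calls and was not left out here. These 2 trends can therefore not be told apart from the shift of that set. The median span was 15165 bp for the mysore-lower calls and 2570 bp for all genes. Over all probe sets with a span, the shift in mysore males was only weakly related to span (rank correlation -0.112). Its median was -0.023 in the shortest group and -0.035 in the longest.

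Among 32 transcripts nearly limited to the accessory gland, those with the sharpest limit differed least. The 7 that were at least 32 times higher in the gland than in the next tissue (CG13965, lectin-46Cb, lectin-46Ca, CG17575, CG9029, Acp32CD and Obp56f) had dahomey minus brownsville differences of 0.30 to 0.50, with a median of 0.33. The other 25 had differences of 0.34 to 0.75, with a median of 0.55. This difference was not tested.

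In alstonville females, 4 immune effector genes were higher than in the rest: BomBc3 (0.65), Mtk (0.31), BomS5 (0.31) and Bbd (0.30), with limma adjusted p under 0.05 for each. With the batch as a block on the arrays none was called, since that contrast had 0 higher and 1 lower, and without als2 it had 1 higher and 2 lower on the line means. In the immune effector list, 1 of 21 probe sets passed the alstonville contrast, and 3 adjusted over the list alone. The list mean was 0.06 above the rest (camera adjusted p = 0.519 with an estimated correlation). Chance could not be excluded for the calls of this contrast, as 24 of 100 pairings of the lines gave as many.

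Yolk and eggshell transcripts were measurable in male arrays and varied between lines. Yp1 had strain means of 8.67 in alstonville, 7.49 in brownsville, 8.50 in dahomey, 7.56 in japan and 7.67 in mysore males, and single lines lay between 7.29 and 9.39. Over the 10 lines Yp1 and Cp36 had r = 0.941 (permutation p = 0.0005), and r = 0.743 without the 2 farthest lines. In females the ejaculatory bulb transcripts Ebp and EbpII were highest in brownsville, at 6.77 and 6.64.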
